A study of Homo sapiens with 12 samples.

How the data were processed

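Long RNA and small RNA of Hs578T breast cancer cells were sequenced from 2D culture (day 0) and 3D organotypic culture (day 6), 3 libraries of each kind per culture, 12 libraries in 4 groups. Per the labels' protocols, ribosomal RNA was removed, long RNA libraries were made with a directional kit and small RNA libraries with a small RNA kit. The RNA of 3D cultures was extracted with minor modifications of the kit's procedure. Groups and replicate numbers were taken from the labels, and table columns were matched to samples by name.

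Per the submitters' processing notes, the genome build was GRCh38 and the tools included Trimmomatic, cutadapt, HISAT2, Bowtie and StringTie, with no versions, roles or order. The first deposited table held estimated counts per transcript, as whole numbers, for 216043 transcripts, 12301 of them assembled. The counting step and its use of strand are not given in the sources used here. Reads were divided among transcripts, so a transcript's estimated count can move to another transcript of the same gene between libraries. The second deposited table held FPKM per transcript, made by the authors. Count divided by FPKM differed between libraries by 1 factor for all transcripts compared, within 0.191% over 5380 transcripts. The third deposited table held miRNA counts and, beside them, TPM values for 1350 known and 86 predicted miRNAs. The deposited TPM equalled the count divided by the library total, times 1e6, with no length term. Total-count scaling and TPM therefore leave in any shift in the makeup of the libraries, such as one from a few abundant RNAs. The FPKM factor was not compared with the library totals. TMM factors take such a shift out on the assumption that most genes do not change, and 50.7% of tested genes passed.

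Estimated counts of a gene's transcripts were added per gene identifier, giving 58469 genes, of which 57754 matched the table of gene names. Loci without a gene name (42) were left out of library sizes and tests. They held between 0.0739% and 0.325% of a library's counts. Classes (protein-coding, lncRNA, pseudogene, small or structural RNA) came from the deposited descriptions and the RefSeq gene table (GRCh38.p14), which also gave the coordinates of the named genes. The planned test assumed counts; the table holds estimated counts in whole numbers, and these were used unchanged.

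The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM factors, filterByExpr), 3D against 2D, for genes, transcripts and miRNAs apart, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values are scaled by TMM factors. The lists, 38 of genes and 10 of miRNAs, were fixed before the data were examined. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it. One gene per symbol entered a list. Lists are named in the results by what they hold. miRNA and host gene changes were compared by Spearman correlation with 100000 permutations. Wilson intervals are at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

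The genes named in the text follow a rule also fixed before the data were examined: the RNAs in the series title, up to 4 members of each list with the smallest p, members at odds with their list, the 10 largest rises and 10 largest falls among genes with a mean log2 CPM of at least 4 whose groups do not overlap, 5 and 5 lncRNAs (at least 2), 6 and 6 miRNAs (at least 5), 5 genes with transcripts moving opposite ways, and the 5 genes of highest CPM. Not every gene the rule gives is printed. Of these, 5 genes are not reported here and do not enter the counts of named genes under the alternatives; they stayed in all tests and list counts.

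Alternatives were DESeq2 1.42.0, RLE factors, total-count scaling, no filter or a stricter one (50 counts, or 10 for miRNAs, in 3 libraries), the replicate number as a block, each library left out in turn, limma on log2(FPKM + 1), log2(FPKM + 0.1), log2(TPM + 1) and log2(TPM + 0.1), and a test against a fold of 2. Replicates of a group were compared by a chi-square test of their counts over genes or miRNAs. The lowest statistic per degree of freedom was 45.9, so no 2 libraries agreed within sampling noise.

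The steps were tested on simulated data drawn from the libraries' means and dispersions, 5 tables each, with 100 features changed 2-fold and 100 changed 4-fold per table. For genes (19105), 25.2% of 2-fold and 77.4% of 4-fold changes were recovered, and 9.68% of calls were false, above the nominal 5%. For miRNAs (531) the shares were 40.4% and 92.4%, with 4.18% false. For transcripts (69086) no change of either size was recovered. A mitosis list lowered 2-fold was called by camera among 37 lists (adjusted p = 2.55e-41), and 0 other lists were called. Genes were drawn independently in the simulation, whereas the estimated correlation within a list reached 0.899 in the data. The simulation therefore does not show how often camera calls lists whose members vary together. The common biological coefficient of variation was 0.284 for genes, 0.853 for transcripts and 0.343 for miRNAs.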

Results

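RNA was measured in Hs578T, an established breast cancer cell line of mesenchymal character, grown either as a flat layer on plastic (2D, day 0) or on a bed of basement membrane extract for 6 days (3D, organotypic culture). Each culture gave 3 libraries of long RNA (mRNA and lncRNA, after removal of ribosomal RNA) and 3 libraries of small RNA, 12 in all. The long RNA libraries held between 42237849 and 51663381 estimated counts and the miRNA libraries between 7061382 and 11586051 counts. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Culture form went together with the day of collection, the medium and a modified RNA extraction in 3D, and these cannot be separated in this design.

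The makeup of the long RNA libraries differed between the cultures. The share of counts on 7SL, 7SK, RMRP and RPPH1, abundant structural RNAs, was 2.04% ± 0.83 (SD, n = 3) in 2D and 5.77% ± 3.00 (SD, n = 3) in 3D. One library, 3D replicate 3, held 9.19% (Wilson 95% interval 9.18 to 9.20, counting error only), with 75.6% of its counts on protein-coding genes against 85.0% and 87.6% in the other 3D libraries. RN7SL1, the 7SL RNA of the signal recognition particle, had the highest mean abundance of all genes. Its log2 fold change of 2.44 (SE 0.93) did not pass edgeR's test (adjusted p = 0.0691), though it did with DESeq2 (0.0382) and the replicate block (0.0186), and without 3D replicate 3 it was 1.19. The other genes of highest abundance were RNA5-8S4, FN1, FP671120.1 and COL6A3. RNA5-8S4, a ribosomal RNA, changed by 0.74 (SE 0.43, adjusted p = 0.194), and by 0.12 without 3D replicate 3. FN1 (fibronectin) changed by 0.84 (SE 0.16, adjusted p = 0.0044), and COL6A3, a collagen VI chain, by 0.30 (SE 0.10, adjusted p = 0.0414). FP671120.1, an unnamed locus classed as a lncRNA, changed by 1.28 (SE 0.37, adjusted p = 0.0267). In the makeup of the libraries FP671120.1 was counted as ribosomal RNA, so its rise may not be that of a lncRNA. Ribosomal RNA held 8.41% of counts in 3D replicate 3, against 4.35% and 3.24% in the other 3D libraries. COL6A3 lost its call without any single one of the libraries 2D 1 to 3, 3D 1 and 3D 2 (log2 fold change 0.26 to 0.34), and it was lower in 3D when libraries were scaled to total counts only (-0.11). Its call was also lost with RLE factors, no filter and the replicate block (adjusted p = 0.0557 to 0.15). FN1 lost its call with total-count scaling (0.46, adjusted p = 0.118) and on FPKM (0.28, adjusted p = 0.424 to 0.524). FP671120.1 lost its call without any 1 of the 2D libraries (1.17 to 1.35) and changed by 0.69 without 3D replicate 3. Its call was also lost with total-count scaling, no filter, the replicate block and FPKM (0.68 to 1.22, adjusted p = 0.0573 to 0.323).

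The first question was how the long transcriptome differed between 3D and 2D culture. Genes of the response to low oxygen were strongly higher in 3D, and genes of DNA replication and mitosis were lower. ANGPTL4, a secreted regulator of lipoprotein lipase, went from 1.06 ± 0.24 to 351 ± 36.7 counts per 1e6 counts (CPM; mean ± SD, n = 3), a log2 fold change of 8.37 (SE 0.23). HILPDA, a lipid droplet protein, rose 73.4-fold, from 11.4 ± 0.83 to 836 ± 71.9 CPM. EDN1, which encodes endothelin 1, fell 91.9-fold, from 143 ± 7.08 to 1.55 ± 0.13 CPM, and DKK1, a secreted Wnt inhibitor, fell 72.2-fold. CCN2, a matricellular protein also known as CTGF, fell from 2286 ± 452 to 70.4 ± 2.75 CPM. With edgeR's quasi-likelihood test, 9678 of 19105 tested genes passed an adjusted p of 0.05, 4941 higher and 4737 lower in 3D, and 5880 of them differed by at least 2-fold. Tested against a fold of 2 in place of 0, 2804 genes passed. Scaling to total counts only lowered the median log2 fold change of all genes by 0.41 (it became -0.37), and 2850 genes were then higher and 6831 lower, so the balance of higher to lower calls rests on the scaling. Directions are given with TMM scaling.

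Among genes with a symbol and a mean log2 CPM of at least 4 whose groups do not overlap, the others of largest rise were DEPP1, a FOXO target (6.15, SE 0.11), GDF15, a stress cytokine (5.95, SE 0.28), CA9, a carbonic anhydrase (5.26, SE 0.43), SYT7, a synaptotagmin (5.26, SE 0.18), ICAM5 (6.32, SE 0.32), the lncRNA AP000317.2 (5.18, SE 0.43), the small nucleolar RNA SNORA73A (9.61, SE 0.67) and IER3 (5.44, SE 1.36). SNORA73A had 2 to 4 counts per 2D library, near the floor, so its fold change depends on the fit. It lies inside SNHG3, which fell by 0.56, and reads of overlapping genes may be shared between them in the counting. IER3 had 3004 counts in 2D replicate 1 and 122 and 199 in the other 2D libraries. Its fold change was 8.21 without 2D replicate 1, and its call was lost without 3D replicate 3 (adjusted p = 0.0668) and with no filter on low counts (0.0881). Within the same limits the others of largest fall were FAM111B (-6.04, SE 0.32), SYNPO2, an actin-bundling protein (-5.23, SE 0.18), HELLS, a chromatin remodeler (-5.18, SE 0.40), GINS4, a subunit of the replicative helicase complex (-4.43, SE 0.32), ADAMTS5, an aggrecanase (-4.41, SE 0.17), MYOCD, a smooth muscle coactivator (-4.34, SE 0.14), and the lncRNA AL133346.1 (-4.80, SE 0.25).

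Of 30 fixed target genes of hypoxia-inducible factors, 29 rose, none fell and 1, STC2, did not pass (-0.10, SE 0.10). Among them NDRG1 rose 23.3-fold to 11229 CPM, BHLHE40 25.3-fold and VEGFA, the angiogenic growth factor, 15.5-fold. The list passed camera (adjusted p = 4.11e-15, and adjusted p = 0.0261 with an estimated correlation). Glycolysis genes rose in 16 of 18 cases, including HK2 (24.0-fold), LDHA (4.64-fold), PGK1 (1.41, SE 0.11) and the lactate transporter SLC16A1 (1.74, SE 0.11). For that list the camera adjusted p was 1.36e-05, and adjusted p = 0.0521 with an estimated correlation. Counts adjusted over the list alone were the same for these 2 lists, 29 and 16. Of 33 nuclear genes of oxidative phosphorylation, 5 rose and 6 fell (4 and 5 adjusted over the list alone). SDHA rose (0.99, SE 0.15), SDHC (-0.96, SE 0.12) and NDUFS1 (-0.74, SE 0.10) fell, and the list did not pass (adjusted p = 0.798). Of 13 genes encoded in the mitochondrial genome 8 fell, for example MT-CO2 (-1.80, SE 0.28) and MT-ND6 (-1.71, SE 0.12), 8 also when adjusted over the list alone. That list passed (adjusted p = 0.0237) and had an adjusted p = 0.594 with an estimated correlation. Mitochondrial mRNA was 0.635% ± 0.043 of counts in 2D and 0.287% ± 0.11 in 3D (SD, n = 3), lowest (0.160%) in 3D replicate 3, the library richest in structural RNA.

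All 30 genes of the G2 phase and mitosis fell. ANLN (anillin, of the cytokinetic ring) was 8.92-fold lower, the kinesin KIF11 6.67-fold lower, KIF23 fell by 2.62 and NDC80 by 2.77 on the log2 scale. Of 30 DNA replication genes 29 fell, among them PCNA, the sliding clamp (6.52-fold lower), UHRF1 (19.4-fold lower), MCM5 (-2.54, SE 0.10) and MCM4 (-2.05, SE 0.09), and RFC4 did not pass (-0.13, SE 0.13). Both lists passed camera (adjusted p = 5.19e-15 and 6.33e-14), also with an estimated correlation (adjusted p = 0.0313 for each). Replication-dependent histone genes fell in 27 of 33 cases, for example H2BC17 (14.8-fold lower) and H2AC17 (-4.08, SE 0.20). Their camera adjusted p was 5.82e-11, and adjusted p = 0.182 with an estimated correlation. Histone mRNAs are near-identical copies, so single members are uncertain. Counts adjusted over the list alone were 30, 29 and 27. Of 22 cell cycle brakes and p53 targets, 6 rose and 9 fell (7 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.943). The cyclin-dependent kinase inhibitor CDKN1A rose (1.86, SE 0.09), as did SESN2 (1.78, SE 0.15) and BBC3 (2.27, SE 0.25), while PLK2 fell (-2.37, SE 0.12). The mean of that list was 0.35 and its median -0.30.

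Genes regulated through YAP and TAZ, effectors of mechanical signalling, were lower. Of 25, 18 fell and 3 rose (19 and 3 adjusted over the list alone). CCN1 was 19.3-fold lower, CRIM1 fell by 2.22 and FGF2 by 2.17 on the log2 scale. F3 (tissue factor, 1.51, SE 0.11), GADD45B (2.07, SE 0.18) and LATS2 (0.43, SE 0.09) rose, LATS2 only where library scaling was not by total counts or FPKM. The list's adjusted p was 4.09e-05, and adjusted p = 0.0524 with an estimated correlation. Of 30 actin and contractility genes, 19 fell and 3 rose, with the same counts adjusted over the list alone. ACTA2, smooth muscle actin, was 9.37-fold lower, ACTG2 fell by 3.00 and VCL (vinculin) by 1.38, whereas TAGLN2 (0.70, SE 0.09) and VIM (0.83, SE 0.17) rose. The calls of TAGLN2 and VIM were lost with total-count scaling (adjusted p = 0.107 and 0.0781) and on FPKM (0.0621 to 0.254). That list had an adjusted p = 0.00126, and adjusted p = 0.157 with an estimated correlation.

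Several matrix genes were higher. Of 21 basement membrane genes 16 rose and none fell (17 adjusted over the list alone), including the laminin chains LAMB3 (3.53-fold), LAMA5 (2.94-fold) and LAMB2 (1.20, SE 0.09). The list's adjusted p was 5.08e-05, and adjusted p = 0.0524 with an estimated correlation. Of 28 fibrillar collagen and matrix genes 18 rose and 5 fell (20 and 5 adjusted over the list alone; adjusted p = 0.0195, and adjusted p = 0.157 with an estimated correlation). LOXL2, a lysyl oxidase, rose (1.78, SE 0.10) and so did BGN (biglycan, 1.96, SE 0.12), while THBS1 (thrombospondin 1) fell from 13427 ± 292 to 1508 ± 192 CPM and FBN2 by 1.66. Of 26 mesenchymal genes 17 rose and 4 fell, with the same counts adjusted over the list alone. TWIST1 rose 5.30-fold and PDGFRB by 1.55, whereas CDH2, which encodes N-cadherin, fell by 1.55, AXL by 0.90 and TAGLN by 1.00 (adjusted p = 0.0623 on FPKM with no filter). That list's adjusted p was 0.0377 (adjusted p = 0.218 with an estimated correlation), and it lost its call without 2D replicate 3 (0.0528) or 3D replicate 2 (0.0517). Of 22 epithelial genes 10 rose, such as DSP (desmoplakin, 1.39, SE 0.11) and KRT17 (1.22, SE 0.13, adjusted p = 0.0512 on FPKM with no filter), and 5 fell, such as TJP1 (-1.02, SE 0.10) and CLDN1 (-1.73, SE 0.23), and the list did not pass (adjusted p = 0.335). Integrins (10 rose, 4 fell of 16, adjusted p = 0.119) and matrix proteases and their inhibitors (14 rose, 8 fell of 28, adjusted p = 0.109) did not pass as lists, with the same counts adjusted over the list alone for all 3. ITGA5 rose 4.29-fold, ITGB8 fell by 2.39, TIMP3 rose 5.44-fold to 10022 CPM and MMP14 rose by 1.78.

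Inflammatory genes driven by NF-kB rose in 25 of 29 cases, and none fell (26 adjusted over the list alone). IL6 rose 18.7-fold, ICAM1 14.1-fold, CXCL8 4.93-fold to 3002 ± 392 CPM and TNFAIP3 by 2.49 on the log2 scale. The list passed (adjusted p = 2.3e-09, and adjusted p = 0.0313 with an estimated correlation). Unfolded protein response genes rose in 17 of 22 cases, with DNAJB9 15.1-fold and HSPA5, the chaperone BiP, 10.6-fold higher, and ATF6 fell by 0.78 (same counts adjusted over the list alone; adjusted p = 4.09e-05, and adjusted p = 0.157 with an estimated correlation). Ribosomal protein genes rose in 29 of 36 cases (33 adjusted over the list alone), for example RPL3 (2.58-fold) and RPS25 (1.16, SE 0.12). Their adjusted p was 5.67e-07, and adjusted p = 0.34 with an estimated correlation, and processed pseudogenes make their counts uncertain. Of 31 lysosome and autophagy genes 16 rose, such as GAA (2.07, SE 0.13) and PSAP (1.65, SE 0.12), and 3 fell, such as LIPA (-1.55, SE 0.24), with the same counts adjusted over the list alone (adjusted p = 0.00985, and adjusted p = 0.131 with an estimated correlation). Of 5 metallothionein and zinc genes 4 rose, MT1X 4.28-fold, also adjusted over the list alone (adjusted p = 0.0399, and adjusted p = 0.195 with an estimated correlation). The metallothionein call was lost without 2D replicate 2 (0.0662) and with the replicate number as a block (0.0562).

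Apart from the lists given with the lncRNAs below, the remaining lists did not pass camera. Immediate early genes (adjusted p = 0.0585) had 12 risen and 4 fallen of 28, with NR4A3 up (3.79, SE 0.17) and FOS down (-2.80, SE 0.11). Of 35 interferon genes 5 rose and 14 fell (6 and 14 adjusted over the list alone; adjusted p = 0.44), with IRF1 up (2.04, SE 0.17). Sterol synthesis had 3 risen and 11 fallen of 24 (adjusted p = 0.105), and fatty acid and lipid genes 7 and 11 of 24 (adjusted p = 0.149), ACACA falling by 1.67. Angiogenic factors had 8 risen and 14 fallen of 27 (9 and 14 adjusted over the list alone; adjusted p = 0.285), with PGF up by 3.53. TGF-beta targets had 10 and 7 of 22 (11 and 7 adjusted over the list alone; adjusted p = 0.342), with SMAD6 down (-2.14, SE 0.13). Amino acid and integrated stress genes had 13 and 10 of 28 (adjusted p = 0.481; DDIT4 up by 4.05, SLC7A11 down, -1.85), and NRF2 and oxidative stress genes 12 and 8 of 29 (adjusted p = 0.335; HMOX1 up by 3.05). Heat shock genes had 5 and 6 of 21 (adjusted p = 0.85), with HSPA4L falling by 1.96. Notch, Wnt and stem cell genes had 10 and 9 of 30 (adjusted p = 0.777; NOTCH3 up by 2.86), and axon guidance genes 14 and 12 of 33 (adjusted p = 0.917; UNC5B up by 3.51). Genes of miRNA processing had 2 and 8 of 19 (adjusted p = 0.245), with DROSHA falling by 1.03 and DGCR8 by 1.43. Where no second count is given, those adjusted over the list alone were the same. Markers of other cell types were few and low. Endothelial markers had 2 risen and none fallen of 8 (adjusted p = 0.729), PECAM1 among them (12.3 to 44.9 CPM), adipocyte and neural markers had 1 risen and 2 fallen of 7 (adjusted p = 0.85), and of 3 tested leukocyte markers, too few for camera, CSF1R rose (1.21, SE 0.18, with the call lost on FPKM, adjusted p = 0.0716 to 0.151). Of the 37 lists tested, 17 passed, 11 higher and 6 lower, and 4 passed with an estimated correlation (hypoxia, mitosis, DNA replication, NF-kB).

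**Figure D1:**
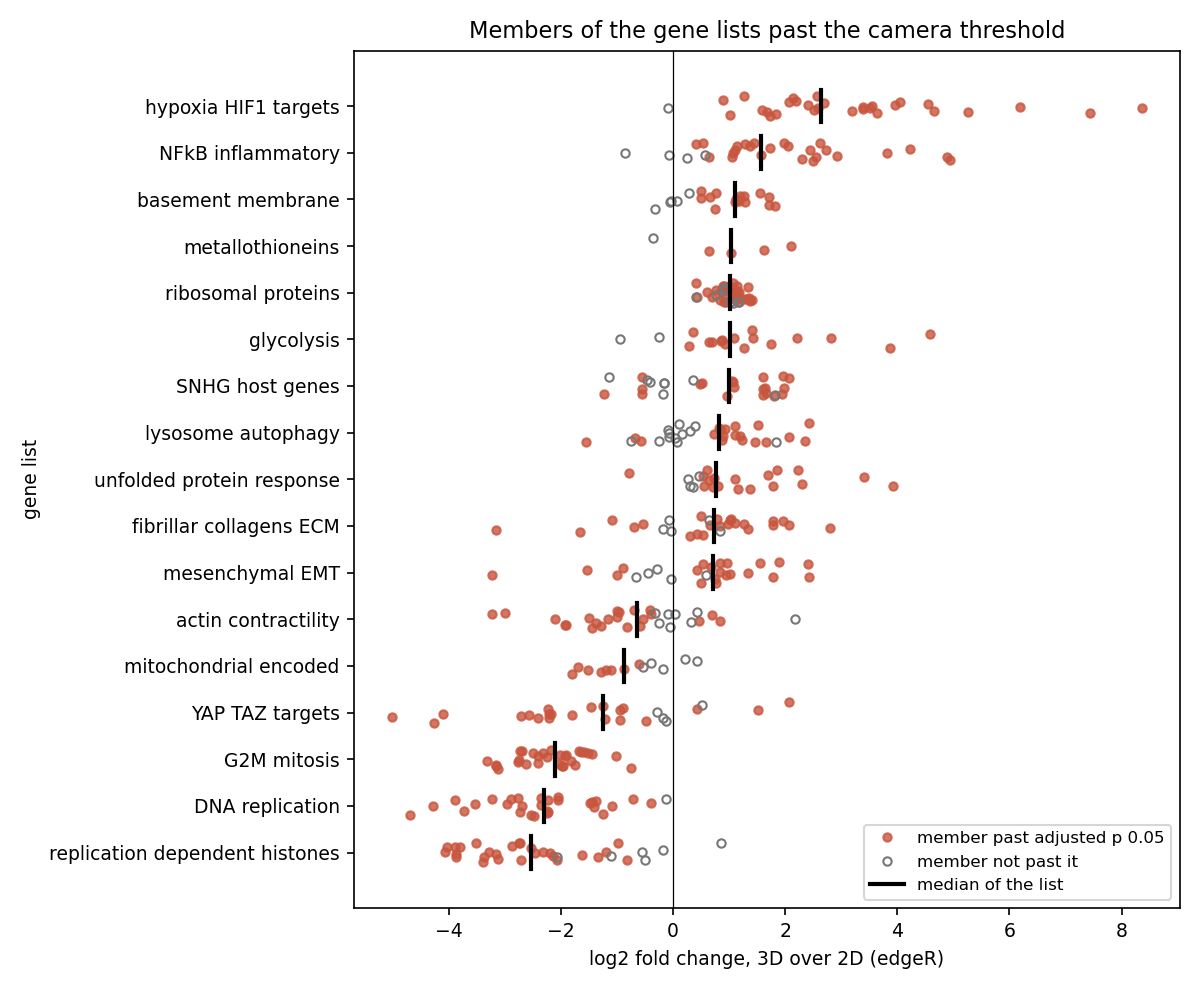
Log2 fold change (3D over 2D) of each tested member of the 17 gene lists that passed camera, 1 point per gene, with the list's median as a bar. Hypoxia targets lie highest, with a median of 2.64, and replication-dependent histones lowest, with a median of -2.54.

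The second question concerned lncRNAs. Of 3413 tested lncRNA genes 1335 passed, 699 higher and 636 lower in 3D, and 412 passed against a fold of 2. With total-count scaling 421 were higher and 963 lower, and on log2(FPKM + 1) 407 and 1083, so this balance too rests on the scaling. HK2-DT, which starts beside HK2, rose from 9.08 ± 0.19 to 189 ± 15.1 CPM (4.38, SE 0.11), and BHLHE40-AS1 rose by 4.29 (SE 0.16) beside BHLHE40. TBC1D22A-DT rose by 4.35 (SE 0.80), or by 3.05 without 3D replicate 3. TGFB2-OT1 (6.67, SE 1.49) had 910, 1345 and 16 counts in the 3D libraries and 9 to 10 in 2D, overlaps TGFB2, and lost its call without 2D replicate 1 (adjusted p = 0.0514), with no filter (0.0583) and on FPKM (log2 fold change 2.50 to 4.17, adjusted p = 0.0504 to 0.132). Among those that fell were AC092807.3 (-4.96, SE 0.26), LINC01224 (-4.49, SE 0.84; -5.48 without 3D replicate 1), LINC02984 (-4.26, SE 0.13) and AP001599.1 (-4.02, SE 0.18). Whether counting used the strand is not stated, so reads of antisense and overlapping genes may be shared with their partners. Of 28 host genes of small nucleolar RNAs 16 rose and 4 fell, with the same counts adjusted over the list alone. SNHG12 rose 3.86-fold, GAS5 3.50-fold, SNHG32 by 1.66 and TAF1D by 1.61, while SNHG4 (-1.23, SE 0.19) and SNHG3 fell. That list passed (adjusted p = 0.0268, and adjusted p = 0.34 with an estimated correlation). Of 38 lncRNAs known from cancer studies 14 rose and 6 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.166). LUCAT1 rose by 1.71, and TUG1 (-1.37, SE 0.20) and LINC01116 (-1.77, SE 0.18) fell.

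The series title names SNHG7, miR-486-3p and HIF1A. SNHG7 (ENSG00000233016), a small nucleolar RNA host gene on chromosome 9 (136724594 to 136728184, GRCh38), rose from 11.9 ± 1.20 to 49.6 ± 17.7 CPM (SD, n = 3), a 4.18-fold difference (log2 2.06, SE 0.25, edgeR adjusted p = 6.82e-04), with all 3D libraries above all 2D libraries. SNORA17A and SNORA17B lie within it, and their reads may be shared with it in the counting. HIF1A (ENSG00000100644), the oxygen-regulated subunit of hypoxia-inducible factor 1, on chromosome 14 (61695513 to 61748258), fell from 470 ± 6.18 to 295 ± 37.6 CPM, 1.59-fold lower (-0.67, SE 0.12, adjusted p = 0.00332), in all 3D libraries. The miRNA hsa-miR-486-3p, from overlapping genes on chromosome 8 (41660441 to 41660508 and 41660444 to 41660507), fell from 599 ± 31.3 to 333 ± 73.6 CPM, 1.80-fold lower (-0.85, SE 0.23, adjusted p = 0.0201). Its call was lost without 2D replicate 1 (adjusted p = 0.0676), 2 (0.0839) or 3 (0.0736), or without 3D replicate 2 (0.096). In every library the hsa-miR-486-3p count was 0.915 to 0.943 times the hsa-miR-486-5p count, whose change was the same within error (-0.85, SE 0.23) and whose call was lost without the same 4 libraries (adjusted p = 0.0674 to 0.0939). Other miRNAs from overlapping genes also had near-equal counts, so reads of the 2 arms may not have been told apart in the counting.

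**Figure D2:**
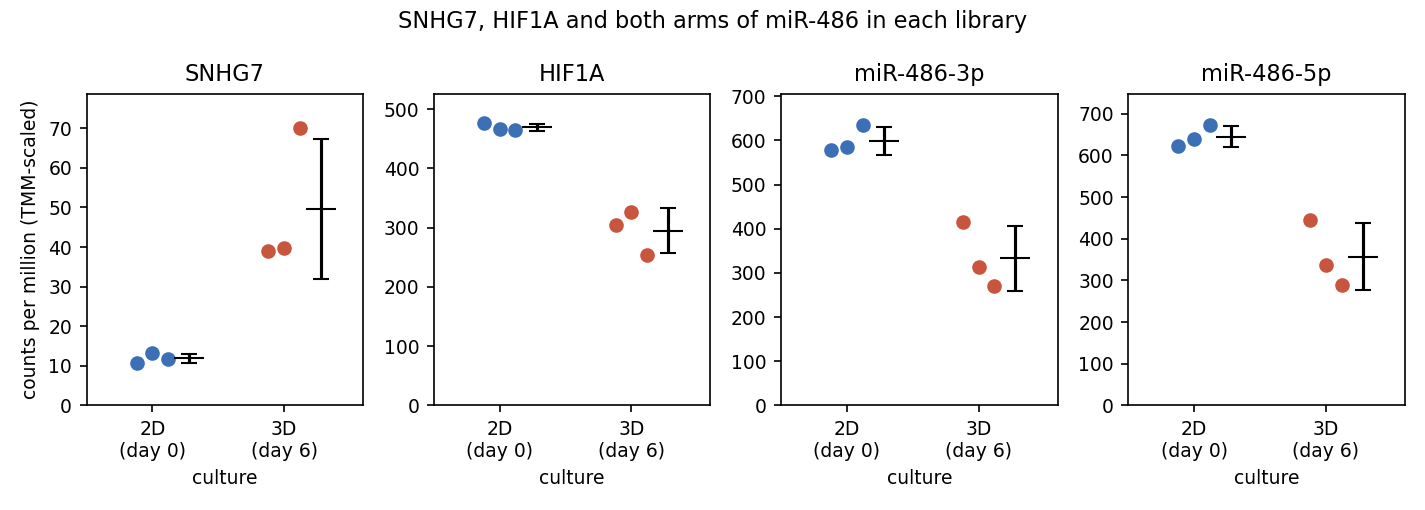
TMM-scaled CPM of SNHG7, HIF1A, miR-486-3p and miR-486-5p in each library, by culture (points, n = 3 per culture; bars give the mean and SD). In each panel the 3D points do not overlap the 2D points: SNHG7 lies higher in 3D, the others lower.

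The third question concerned miRNAs. Of 531 tested, 177 passed, 86 higher and 91 lower in 3D. The miRNA miR-21-5p rose from 23711 ± 3560 to 107850 ± 16577 CPM (2.19, SE 0.23), miR-143-3p from 6395 ± 905 to 17721 ± 2884 (1.47, SE 0.22), and miR-199a-5p by 1.63 (SE 0.23). Of 23 mesenchymal miRNAs 9 rose, none fell and 14 did not pass (11 rose adjusted over the list alone). Among miRNAs with a mean log2 CPM of at least 5 whose groups do not overlap, the largest rises beside that of miR-21-5p were those of hsa-miR-30b-5p (4.14, SE 0.82), hsa-miR-16-5p (2.48, SE 0.64), hsa-miR-320d (2.24, SE 0.34), hsa-miR-186-5p (2.10, SE 0.34) and hsa-miR-15b-5p (2.06, SE 0.53). 3 of these rested in part on 3D replicate 3: without it hsa-miR-30b-5p changed by 2.63, hsa-miR-16-5p by 1.21 and hsa-miR-15b-5p by 1.15. The call of hsa-miR-16-5p was lost without any 1 of the 2D libraries (adjusted p = 0.065 to 0.0727), and that of hsa-miR-15b-5p without 2D replicate 1 (0.0695) or 3 (0.0658). The calls of hsa-miR-16-5p and hsa-miR-30b-5p were also lost with no filter (0.202 and 0.138), that of hsa-miR-15b-5p with total-count scaling (0.0528), and those of hsa-miR-16-5p and hsa-miR-15b-5p on TPM (0.117 to 0.146). Within the same limits the largest falls were those of hsa-miR-365b-5p (-2.85, SE 0.32), hsa-miR-7704 (-2.63, SE 0.42), hsa-miR-23a-5p (-2.36, SE 0.29), hsa-miR-195-3p (-2.34, SE 0.32), hsa-miR-99b-3p (-2.10, SE 0.23) and hsa-miR-615-3p (-1.93, SE 0.41). The last lost its call without 3D replicate 2 (adjusted p = 0.0509) and changed by -2.56 without 3D replicate 1. These are changes of single arms. Where both arms of such a hairpin had a mean count of at least 50, the other arm moved less or the other way. Beside the falls, hsa-miR-23a-3p changed by 1.49, hsa-miR-195-5p by 1.31 and hsa-miR-99b-5p by -0.20. Beside the rises, hsa-miR-30b-3p changed by -0.66, hsa-miR-21-3p by -0.19 and hsa-miR-15b-3p by 0.29. The cause was not tested. The most abundant miRNA, let-7i-5p, took 45.9% ± 4.07 of counts in 2D and 45.4% ± 6.65 in 3D (SD, n = 3). The number of calls was 106 without 2D replicate 2, 110 without 2D replicate 3 and 113 without 3D replicate 2. With total-count scaling 39 miRNAs were higher and 84 lower.

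In the miR-29 and miR-30 group 6 rose and 1 fell of 11 (hsa-miR-30c-5p 1.76, SE 0.25), with the same counts adjusted over the list alone. In the miR-200 family 1 rose and 3 fell of 6, also adjusted over the list alone, with hsa-miR-200a-5p lower (-1.57, SE 0.24). The calls of hsa-miR-200b-3p (-0.73, SE 0.22), hsa-miR-200b-5p (-1.30, SE 0.39) and hsa-miR-200a-3p (0.93, SE 0.28) were each lost without any 1 of the 2D libraries or without 3D replicate 2 (adjusted p = 0.0531 to 0.143), the first also without 3D replicate 3 (0.0511). They were lost with no filter (0.0518 to 0.0915) and on TPM with no filter (0.112 to 0.471), the first and last with the replicate block (0.0619 and 0.0597), and the last with total-count scaling (0.207) and TPM (0.235 to 0.237). Of 8 hypoxia-linked miRNAs, hsa-miR-210-3p (0.88, SE 0.26, adjusted p = 0.029) was higher and hsa-miR-210-5p lower (-1.61, SE 0.40), with 2 higher and 2 lower adjusted over the list alone. The call of hsa-miR-210-3p was lost without any 1 of the 2D libraries (adjusted p = 0.074 to 0.11) or without 3D replicate 2 (0.0554), and that of hsa-miR-210-5p without 2D replicate 3 (0.0661) or 3D replicate 2 (0.063). Total-count scaling also ended both calls (0.197 for hsa-miR-210-3p and 0.0531 for hsa-miR-210-5p), and the replicate block (0.0575) and TPM (0.279 to 0.471) that of hsa-miR-210-3p. The let-7 family had 1 higher and 1 lower of 9, the miR-17-92 clusters 1 lower of 8 (hsa-miR-106b-3p -1.35, SE 0.22), the miR-34 and p53 group 3 higher of 9, the inflammatory miRNAs 3 higher of 7 and the erythroid and leukocyte miRNAs 2 lower of 3, both miR-486. The other arm of the miR-106b hairpin, hsa-miR-106b-5p, did not pass (1.44, SE 0.56, adjusted p = 0.0725). Of 3 muscle, liver and neural miRNAs none passed. Adjusted over the list alone these counts did not change. Most of the calls in the let-7, p53 and inflammatory groups were weak. The let-7 rise, hsa-miR-98-5p (0.90, SE 0.28), was lost in 9 of 15 alternatives, among them each 2D library left out (adjusted p = 0.0987 to 0.114) and 3D replicate 2 (0.0553), and the let-7 fall, hsa-let-7e-5p (-0.86, SE 0.20), without 2D replicate 2 (0.0809) or 3D replicate 2 (0.0651). In the p53 group hsa-miR-194-5p (1.51, SE 0.44) was lost in 9, among them each 2D library left out (0.0534 to 0.102), 3D replicate 2 (0.0687) and 3D replicate 3 (0.0548), and hsa-miR-192-5p (1.13, SE 0.27) in 6, among them 2D replicate 2 (0.0661) and 3 (0.0562) left out. Of the inflammatory miRNAs hsa-miR-146b-5p (0.88, SE 0.27) was lost in 8, among them each 2D library left out (0.0644 to 0.131) and 3D replicate 2 (0.0751), and hsa-miR-146a-5p (0.96, SE 0.23) in 6, among them 2D replicate 2 (0.0542) and 3 (0.0658) left out. All 5 that rose also lost their call with total-count scaling (0.0853 to 0.155) and on TPM (0.0757 to 0.432).

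**Figure D3:**
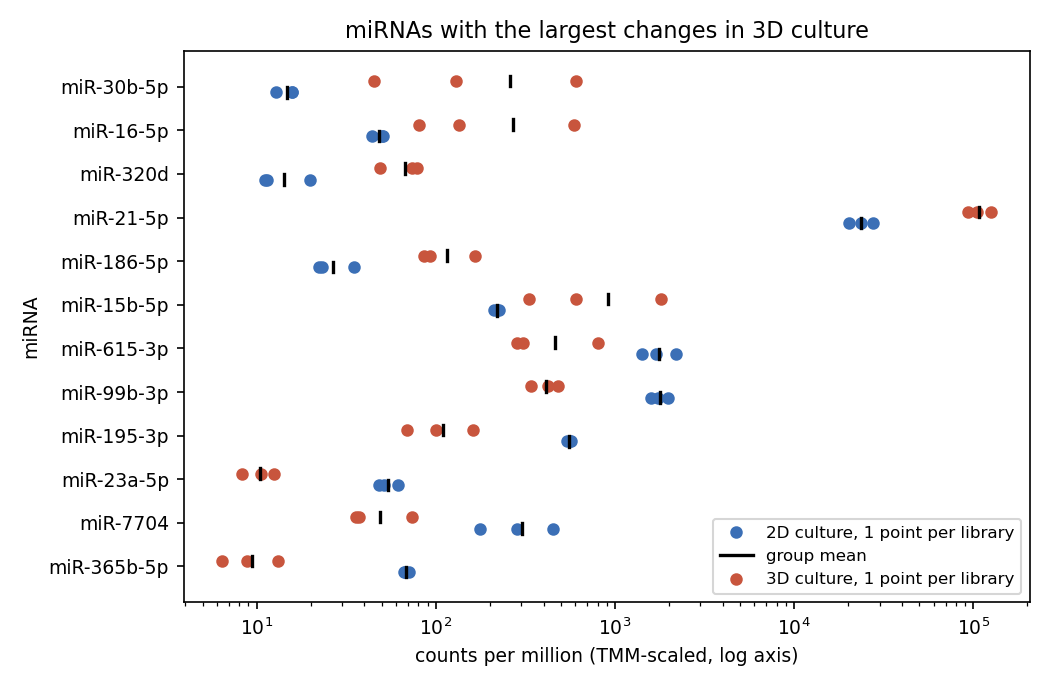
TMM-scaled CPM, on a log axis, of the 6 miRNAs with the largest rise and the 6 with the largest fall among those with a mean log2 CPM of at least 5 whose groups do not overlap, 1 point per library with the group mean as a bar. In each row the 3 libraries of 3D culture lie on one side of the 3 of 2D culture, miR-21-5p being the most abundant.

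The miRNA changes were compared with those of the genes that contain them, over 60 host genes with 1 miRNA each. Some of these miRNAs, such as miR-24-3p and miR-29b-3p, come from more than 1 gene but were set against 1 host. Their counts need not follow that host, so a correlation near 0 does not show that miRNAs and hosts are uncoupled. Across genes, which are not independent replicates, the Spearman correlation was -0.06 (permutation p = 0.657, two-sided, 1 relation tested as the main one). In 15 pairs both members passed, and 5 of these moved the same way. Examples of opposite change are miR-21-5p with VMP1 (fell by 1.19) and miR-143-3p with CARMN (fell by 1.23). One of like change is miR-455-5p (1.25) with COL27A1 (1.53), though the other arm, miR-455-3p, did not pass (0.0053, adjusted p = 0.988). All 3 examples were chosen after their values were seen.

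At the level of transcripts 5297 of 69086 passed, 2595 higher and 2702 lower. P4HB, a collagen-modifying chaperone, had transcript ENST00000415593 at 281 CPM in 3D and 0 in 2D, while ENST00000575069 fell from 251 to 2.21 CPM. TACC1, ATP2B4, AZIN1 and TRAK2 likewise each had 1 transcript that rose and 1 that fell, among 194 genes with such a pair. These counts are estimates that divide reads among transcripts, and single transcripts switched between replicates: the EEF1A1 transcript ENST00000331523 had 246941, 206895 and 7912 counts in 2D and 0, 366129 and 522879 in 3D. The number of calls was 142, 153 and 207 without 2D replicate 1, 2 and 3, and 235, 1541 and 3592 without 3D replicate 1, 2 and 3. It was 0 with the replicate number as a block. Of the SNHG7 transcripts ENST00000416970 rose from 1 count in each 2D library to 317, 459 and 649 in 3D. The assembled transcript TCONS_00032822 rose from 6.06 to 26.8 CPM (adjusted p = 0.0327). Its other tested transcripts did not pass: ENST00000447221 (0.45, adjusted p = 0.459), ENST00000436596 (2.48, adjusted p = 0.31) and ENST00000414282 (-0.97, adjusted p = 0.201). The rise of SNHG7 thus rests in large part on an assembled transcript. None of the 7 tested HIF1A transcripts passed.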

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

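Leaving out structural RNAs, keeping 1 miRNA of each overlapping pair and leaving out replicates in the host gene comparison were chosen after seeing the data. SNHG7 (log2 1.62 to 2.21) and HIF1A (-1.07 to -0.58) kept direction and call in all 16 alternatives. hsa-miR-486-3p stayed lower in 15 (-1.11 to -0.69; -1.01 to -0.69 with a replicate left out, adjusted p 0.00175 to 0.096), with the call lost in 4, where fewer samples entered. Counts moved by over 1.5 times as follows, though the ranges with a library left out also hold smaller moves. The cause of these moves was not tested, and fewer samples entered where a library was left out. Against a fold of 2, 2804 genes and 412 lncRNAs passed. Transcripts numbered 16156 with DESeq2, 1807 without a filter, 0 with the replicate block, 9936 on log2(FPKM + 1), 9579 on log2(FPKM + 0.1) and 142 to 3592 with a library left out. miRNAs numbered 89 on log2(TPM + 1) without a filter and 106 to 240 with a library left out. Gene lists numbered 4 with an estimated correlation and 31 with fry, which tests each list by itself. With a library left out, genes numbered 7730 to 10228 and lncRNAs 988 to 1374; DESeq2 gave 10343 genes, 9620 of them also in the main set. FPKM scaling gave 2722 genes higher and 6773 lower on log2(FPKM + 1), and log2(TPM + 1) gave 35 miRNAs higher and 100 lower, in each case a lower share of rises than with TMM. The correlation of miRNAs with host genes stayed between -0.20 and -0.02, with no permutation p under 0.438.

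Of the named genes, 10 of 2232 values under other settings reversed and 73 lost their call. COL6A3 was -0.11 with total counts and -0.16, -0.16 and -0.16 on the FPKM settings (log2(FPKM + 1), log2(FPKM + 0.1), no filter). LATS2 was -0.0207, -0.0237 and -0.0207, and SREBF2 -0.10, -0.10 and -0.10 on the same 3. These settings leave in the shift of the median. With a library left out 35 of 1344 lost their call, and none reversed. Of the named miRNAs 51 of 405 lost it, and 48 of 270 with a library left out.

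Same-numbered libraries did not deviate together beyond a correlation of 0.108 (genes, 0.0305 to 0.108; miRNAs, -0.0721 to 0.0561), so the numbers were not taken as pairs. Each long RNA library did correlate best with its own number, a hint from the data. Of the miRNA libraries only replicate 3 of each culture did (0.0561). With the replicate block 9233 genes, 1179 lncRNAs, 154 miRNAs and 16 gene lists passed. SNHG7 changed by 2.01, HIF1A by -0.68 and hsa-miR-486-3p by -0.87, and the host gene correlation was -0.0778. The simulation recovered 25.2% of 2-fold gene changes and no transcript change of either size. It changed only 100 features 2-fold and 100 features 4-fold at a time. In the data 9678 of 19105 genes and 5297 of 69086 transcripts passed. With so few changed features, the Benjamini-Hochberg adjustment asks for smaller p-values than it did in the data. The recovered shares therefore cannot show how many changes were missed at this depth and number of libraries.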

Other observations

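The tests of miR-486 and of HIF1A below were chosen after their results were seen; those on neighbouring genes and on splits of the samples were not. EPAS1, which encodes the HIF-2 alpha subunit, rose 4.88-fold (2.29, SE 0.11, edgeR adjusted p = 1.69e-05, higher in 3 of 3 libraries of 3D culture), and ARNT, the shared partner of both alpha subunits, rose by 0.61 (SE 0.12). Both were chosen after their values were seen. ANK1, whose locus holds the miR-486 genes, fell by 2.32.

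Counts of miR-486-3p followed those of miR-486-5p. miRNA genes that overlap in position in RefSeq gave a pair of miRNAs within 25% of each other in all 6 libraries in 10 of 10 cases, 1 of them miR-486 itself, which prompted the test. Without miR-486 these were 9 of 9, for example miR-214-5p with miR-3120-3p and miR-24-3p with miR-3074-5p. Of pairs of miRNA genes that lie within 10000 bases without overlapping, 0 of 235 did so (Fisher's exact test, p = 1.37e-16). Many of the 235 pairs share a miRNA within a cluster and are not independent, so the size of this p-value cannot be relied on. Near-equal counts at overlapping genes are what counting without regard to strand would give. They may mean that most counts listed under miR-486-3p are miR-486-5p reads. A separate pool of 3p molecules would vary against the 5p arm as in other hairpins, but the SD of the log2 ratio over the libraries was 0.0161, below all 69 hairpins outside the near-equal pairs (lowest 0.151, median 0.738). Of all 75 other hairpins 1 was lower, miR-3158, itself from overlapping genes. How much miR-486-3p was present stays open without the reads.

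HIF1A mRNA was lower in 3D while 29 of 30 targets of hypoxia-inducible factors rose. Library scaling stays open: the highest HIF1A log2 fold change over 7 other scalings was -0.686, but each of them lowers the median of all genes, so none could have raised it. Reads moved to genes that overlap HIF1A in RefSeq are not the source, since the sum of HIF1A, HIF1A-AS1 and HIF1A-AS3 changed by -0.667 (SE 0.115). The deposited gene models can reach further than RefSeq's, which this sum would miss. HIF1A mRNA relative to other genes was lower at day 6 (-0.6702, SE 0.12), also in all 16 alternatives (-1.07 to -0.58). The scalings among these could not have raised it. This argues against more HIF1A mRNA relative to other genes at day 6, as release from a falling miR-486-3p might give, as the source. An earlier rise, or one in absolute amount, was not measured and stays open. Protein levels, HIF-2 (EPAS1 rose) and the differing day, medium and extraction stay open and were not tested.

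Noncoding genes named for a coding neighbour moved with it. Over 908 pairs the Spearman correlation of their fold changes was 0.458 across genes, which are not independent replicates (permutation p = 1e-05, the smallest 100000 permutations can give, adjusted 1.2e-05 over 6 relations). Reads counted for both genes may add to this where they overlap (0.528, 569 pairs), but the 276 pairs that do not overlap in RefSeq still gave 0.302 by the same permutation test. The deposited gene models can reach further than RefSeq's, which this test would miss. The 101 pairs without overlap and with a mean log2 CPM of at least 1 gave 0.508. Noise from low counts would weaken a correlation rather than make one, so this could not test them as a source. Of the 47 of these in which both genes passed, 39 moved the same way. Examples are HK2-DT (4.38) with HK2 (4.59) and SLC12A2-DT (-1.61) with SLC12A2 (-1.31), while WAC-AS1 (-1.41) and WAC (0.91) did not. A shared local control of neighbouring genes is a candidate explanation, as a hypothesis.

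The 6 libraries of a kind can be divided 3 against 3 in 10 ways, too few for a share under 0.05, and only 1 of them, the real one, reached the real count in each case. The real split gave 9678 genes, 1335 lncRNAs, 5297 transcripts and 177 miRNAs, and the highest of the other splits gave 0 in each, by edgeR. For gene lists the real split gave 17 and the highest other split 13. Each other split still sets 2 libraries of one culture and 1 of the other against the rest. The culture difference then adds to the spread within groups, so the counts of 0 say little about the real split.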
